A study of Mus musculus with 12 samples.

How the data were processed

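RNA was sequenced from 12 libraries of mouse mesenchymal stromal cell preparations, 3 in each of 4 groups. Marrow cells from the hind limbs and pelvis of wild-type mice were plated on collagen I, and after the first passage they were either used directly (BM nonsorted) or sorted by flow cytometry for cells positive for CD51 and Sca-1 and negative for CD31, CD45, Ly6C and F4/80 (BM sorted). Bone-associated cells (BAC) came from hind-limb bone fragments digested with collagenase I and were either used directly (BAC nondepleted) or freed of cells carrying CD45, Ly6C or F4/80 with magnetic beads (BAC depleted). Per the labels' protocols, RNA was purified on columns and 50 ng entered a low-input library kit, and the marrow medium held no ascorbic acid under hypoxia. How long the bone-associated cells were cultured before RNA was taken is not given in the sources used here.

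The deposited table holds raw read counts per gene for all 12 libraries. Per the submitters' processing notes, the tools were STAR 2.7.9a, featureCounts from Subread 2.0.1 and MultiQC 1.7, and the genome build was GRCm39. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. Gene symbols are those of the table. No coordinates are given, because the reference genome held here is of another build. Of 53819 entries of the table, 22808 had 0 counts in all libraries, and 38138 matched a RefSeq symbol. The 1442 entries without a symbol held 0.013% to 0.0297% of the counts of a library. They were not removed, so those that passed the low-count filter entered library sizes and tests.

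Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were left out with filterByExpr on the groups, and 15698 genes were tested. One model with a mean per group was fitted to all 12 libraries, with a common dispersion of 0.0969 and 8 residual degrees of freedom, and each comparison was a contrast in edgeR's quasi-likelihood F test with robust dispersions. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes carry an approximate standard error (SE), the size of the fold change divided by the square root of the F statistic. Near 0 counts this SE is not a reliable measure of precision. Levels are in CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. The 5 contrasts were BM sorted minus BM nonsorted, BAC depleted minus BAC nondepleted, BM sorted minus BAC depleted, BM nonsorted minus BAC nondepleted, and the difference between the first and the second. The overlap of calls was computed only between comparisons that share no library, against the product of both numbers of calls divided by the genes tested, per direction.

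A gene with 0 counts in all libraries of a group has its ratio given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval, since the fitted value then depends on the prior count. Floors and intervals cover counting error only, because reads from amplified libraries are not independent molecules. Gene groups were tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Each result was also computed with an estimated correlation. Of 30 lists of markers and processes, 28 had at least 3 tested genes. Beside each list stand the members that passed over all genes and those that passed when adjusted over the list alone. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes. The design, the lists, the alternative settings and the rule for naming genes were fixed before the data were examined.

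The rule named, per comparison of 2 groups, the 7 markers of the sort and the depletion, and the 6 genes with the largest rise and the 6 with the largest fall by fitted log2 fold change, an order that depends on the prior count where counts are near 0. These had to be called, show no overlap between the libraries of both groups and reach at least 5 CPM in the higher group, and predicted models, Rik clones and pseudogenes were left out. It also named up to 2 members that rose and 2 that fell in each list, or the most abundant member where none passed. For the difference of the effects it named 5 genes each way without the overlap condition. Other genes named in the closing section were chosen after their values were seen.

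The labels number the libraries of each group 1 to 3 and do not say whether these came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical in part. Alternatives were DESeq2 size factors, upper quartile scaling, the DESeq2 1.42.0 Wald test with adjusted p of NA kept as NA, no low-count filter, a stricter filter of at least 1 CPM in 3 libraries with a mean of 5 CPM in a group, and fits on the compared groups alone. Others were the replicate number as a block, lists without genes that stand on more than one, and leaving out each library in turn. An alternative without BAC depleted replicates 1 and 3 was added after seeing the data. It leaves 1 library in that group, so the spread then comes from the other groups.

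The procedure was tested on simulated counts with the real library sizes and 200 changed genes in each comparison. Each gene had 1 mean and 1 dispersion, taken over all groups. The larger spread within BAC depleted is therefore not represented. In the simulation of BM sorted minus BM nonsorted, run on 15422 genes, edgeR recovered 2 of 67 genes changed 1.5-fold, 16 of 67 changed 2-fold and 47 of 66 changed 4-fold, and called 0 unchanged genes, where DESeq2 called 46. For BAC depleted minus BAC nondepleted, on 15433 genes, the recovered genes were 1, 20 and 51. For BM sorted minus BAC depleted, on 15423 genes, they were 2, 15 and 41. For BM nonsorted minus BAC nondepleted, on 15376 genes, they were 4, 19 and 38. For the difference of the effects, on 15438 genes, they were 0, 5 and 37. In each of the 5 simulations camera called the changed set of 20 genes and 0 of 20 unchanged sets. Genes were drawn independently of each other, so this does not test the preset correlation on correlated lists. The estimated correlation of the cell-cycle list, for one, was 0.694 on marrow sorting. Figures were drawn with matplotlib 3.10.9.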

Results

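Mesenchymal stromal cells (MSC), the non-haematopoietic support cells of bone and marrow, were profiled by RNA sequencing from marrow cultures and from bone-associated cells (BAC), each before and after removal of other cell types. The series concerns how purified stromal cells from both niches differ and how they relate to macrophages. Each of the 4 groups held 3 libraries, with 27937709 to 32164725 counts per library. Correlations of log2 CPM within groups were 0.982 to 0.992 for BM sorted, 0.976 to 0.985 for BM nonsorted, 0.965 to 0.981 for BAC nondepleted and 0.940 to 0.947 for BAC depleted. The chi-square per degree of freedom between libraries of a group was at least 15.6, so libraries of a group differed beyond counting noise, which does not tell separate cultures from repeat preparations. The first principal component held 67.6% of the variance and separated purified from unpurified libraries, and the second held 24.9% and separated marrow from bone-associated libraries.

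**Figure D1:**
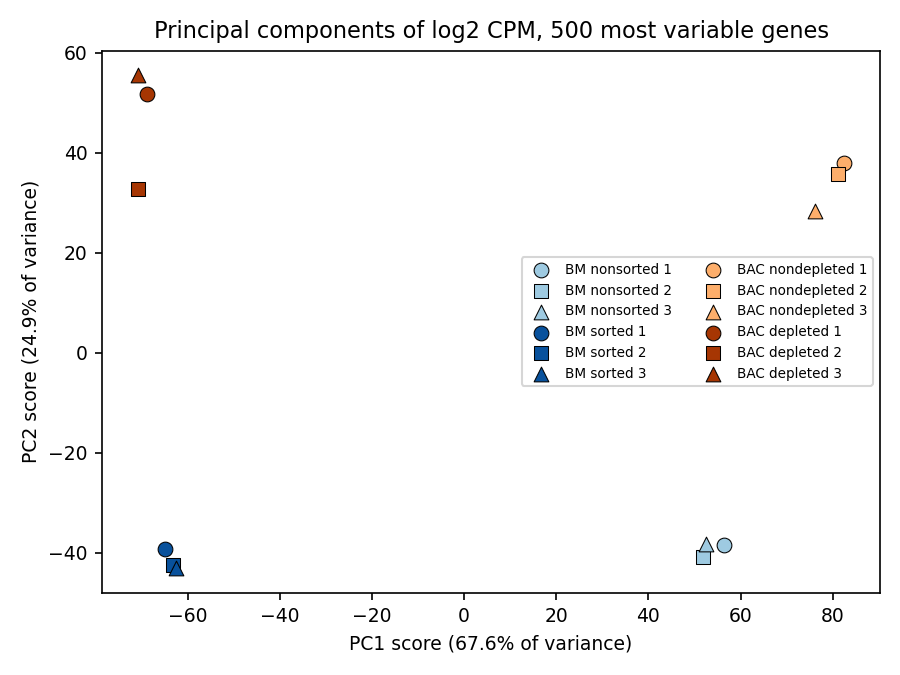
Each point is 1 library, placed by its scores on the first principal component (67.6% of the variance) and the second (24.9%) of log2 CPM over the 500 most variable genes. Colours mark the 4 groups and symbols the replicate number, and the 3 libraries of each group lie together.

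Library 1 of BAC depleted differed from its group in several respects. It held 43406 counts of Xist, the RNA that silences an X chromosome, and 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The other 11 libraries held at most 16 counts of Xist and 72.7 to 244 CPM of Ddx3y. This is the pattern of female cells in BAC depleted 1 and of male cells elsewhere. BAC depleted 1 therefore had another source than BAC depleted 2 and 3 and than BAC nondepleted 1. Mitochondrial transcripts took 2.62%, 2.05% and 1.82% of the counts in the 3 BAC depleted libraries and 1.08% to 1.36% in the other groups. In BAC depleted 3 a single gene, Thbs1, which encodes the matrix protein thrombospondin 1, took 8.11% of the counts. These features enter the 3 contrasts that use BAC depleted: the depletion, the comparison of the purified groups and the difference of the effects.

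Flow sorting of the marrow cultures was compared with the unsorted cultures to find what the sort removed. It removed the transcripts of macrophages almost completely, and few genes were called higher. Ptprc, which encodes CD45, fell from 95.7 ± 10.4 CPM (SD, n = 3) to 0.0402 ± 0.0457, and Adgre1, which encodes F4/80, fell from 302 ± 21.6 to 0.0640 ± 0.0355. Of the positive markers, Itgav, which encodes CD51, stood at 474 ± 25.5 CPM after and 472 ± 99.9 before sorting, and Ly6a, which encodes Sca-1, at 145 ± 5.45 and 185 ± 66.9. Ly6c1, which encodes a form of the Ly6C antigen used to exclude cells, stood at 41.7 ± 1.08 and 42.6 ± 4.69 CPM.

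By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 978 of 15698 genes differed, 26 higher and 952 lower after sorting, and 733 of them had a log2 fold change of at least 1 in size. The 26 rises numbered 7 without BM sorted 1, 6 without BM nonsorted 1, 10 without BM nonsorted 3, 16 without BM sorted 3, 63 with upper quartile scaling, 118 with only the groups compared and 155 with the DESeq2 Wald test. For 28.7% of the genes the 3 libraries of both groups did not overlap, against 10% by chance. Log2 fold changes were -11.03 ± 0.41 for Ptprc (adjusted p = 5.38e-07) and -12.14 ± 0.41 for Adgre1 (2.82e-08), and the differences of Itgav (0.01 ± 0.21, adjusted p = 0.998), Ly6a (-0.35 ± 0.25, 0.619) and Ly6c1 (-0.03 ± 0.42, 0.99) did not pass. Ly6c2 and Pecam1, which encodes CD31, had too few counts to be tested. The genes with the largest fitted falls were myeloid, in an order that rests on the prior count. Fcgr2b, an inhibitory Fc receptor, was at least 2201-fold lower and Clec4d, a C-type lectin, at least 1404-fold lower. Msr1, a scavenger receptor, was lower by a ratio of 13839 (95% counting interval 2483 to 546662), and C1qc by 10721 (3668 to 51991). C1qa and C1qb, which encode the other two chains of complement C1q, had log2 fold changes of -12.96 ± 0.43 and -12.92 ± 0.44 (adjusted p = 2.56e-07 and 2.97e-07).

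The macrophage list moved as a block on sorting: 19 of 20 members fell, 0 rose and 1 did not pass, 20 fell when adjusted over the list alone, and the camera adjusted p was 3.88e-184. Of 14 pan-haematopoietic genes 13 fell and 1 did not pass, 14 fell when adjusted over the list alone, and the camera adjusted p was 8.4e-126. Cd52, a surface glycoprotein of leukocytes, was lower by a ratio of 1761 (487 to 14545). Of 16 inflammatory cytokines and chemokines 7 fell and 9 did not pass, 7 fell when adjusted over the list alone, and the camera adjusted p was 2.65e-08. Among them Ccl4, a macrophage chemokine, was at least 242-fold lower, and Tnf was lower by a ratio of 543 (150 to 4488). Of 7 osteoclast genes 3 fell and 4 did not pass, 3 fell when adjusted over the list alone, and the camera adjusted p was 1.58e-05. Tnfrsf11a, the receptor for the osteoclast signal RANKL, fell by 6.93 ± 0.29 on the log2 scale (adjusted p = 1e-06). Of 5 gate markers 2 fell and 3 did not pass, also 2 when adjusted over the list alone, and the camera adjusted p was 4.36e-17. The 2 that fell, Ptprc and Adgre1, encode antigens the sort selected against, so their fall was set by the procedure. The list also holds Itgav and Ly6a, which encode antigens the sort selected for. In the erythroid and megakaryocyte list only Pf4, a platelet chemokine, fell (-9.76 ± 0.45, adjusted p = 2.56e-07) and 2 of 3 members did not pass, also 1 when adjusted over the list alone (camera adjusted p = 0.00062). The median of 0.26 has the opposite sign to the mean of -3.02. These 6 lists stayed called with an estimated correlation, at adjusted p of 1.52e-05 (macrophage), 4.98e-05 (pan-haematopoietic), 0.0402 (inflammatory), 0.00921 (osteoclast), 0.000197 (gate markers) and 0.0402 (erythroid and megakaryocyte).

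The other 22 lists were not called after sorting (camera adjusted p of 0.137 to 0.941), and 14 of them had no member that passed. Cxcl12, the chemokine that holds haematopoietic stem cells in the marrow, stood at 6904 ± 5001 CPM in BM sorted and 3071 ± 1368 in BM nonsorted (1.17 ± 0.63, adjusted p = 0.453). BM sorted 1 held 377616 counts of Cxcl12, against 138480 and 126929 in libraries 2 and 3, and BM nonsorted held 50108, 109974 and 142742. None of 20 cell-cycle genes passed by edgeR, also 0 when adjusted over the list alone (camera adjusted p = 0.927). The few genes that rose included Lbp, a lipopolysaccharide-binding protein (1.35 ± 0.23, adjusted p = 0.00427), and Slc2a3, a glucose transporter (1.7 ± 0.36, 0.0168). Smaller rises were seen for Serpine2 (1.27 ± 0.32, 0.0442), Hilpda (1.24 ± 0.30, 0.0356), Pcx (0.99 ± 0.23, 0.0282) and Clmp (0.92 ± 0.22, 0.0316). With 1 library left out the log2 fold changes were 1.37 to 2.10 for Slc2a3, 1.08 to 1.51 for Serpine2, 1.13 to 1.44 for Hilpda, 0.77 to 1.12 for Pcx and 0.68 to 1.07 for Clmp, and each of these 5 calls was lost in several of those fits. Without BM sorted 1 the adjusted p was 0.0708 for Slc2a3, 0.172 for Serpine2, 0.131 for Hilpda, 0.12 for Pcx and 0.127 for Clmp, and without BM nonsorted 1 or BM nonsorted 3 all 5 were lost as well (0.0848 to 0.191). Serpine2 (0.073), Hilpda (0.0787) and Pcx (0.0591) were also lost without BM sorted 2, Serpine2 (0.0992), Hilpda (0.0845) and Clmp (0.0576) without BM sorted 3, and Pcx (0.0624) without BM nonsorted 2.

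**Figure D2:**
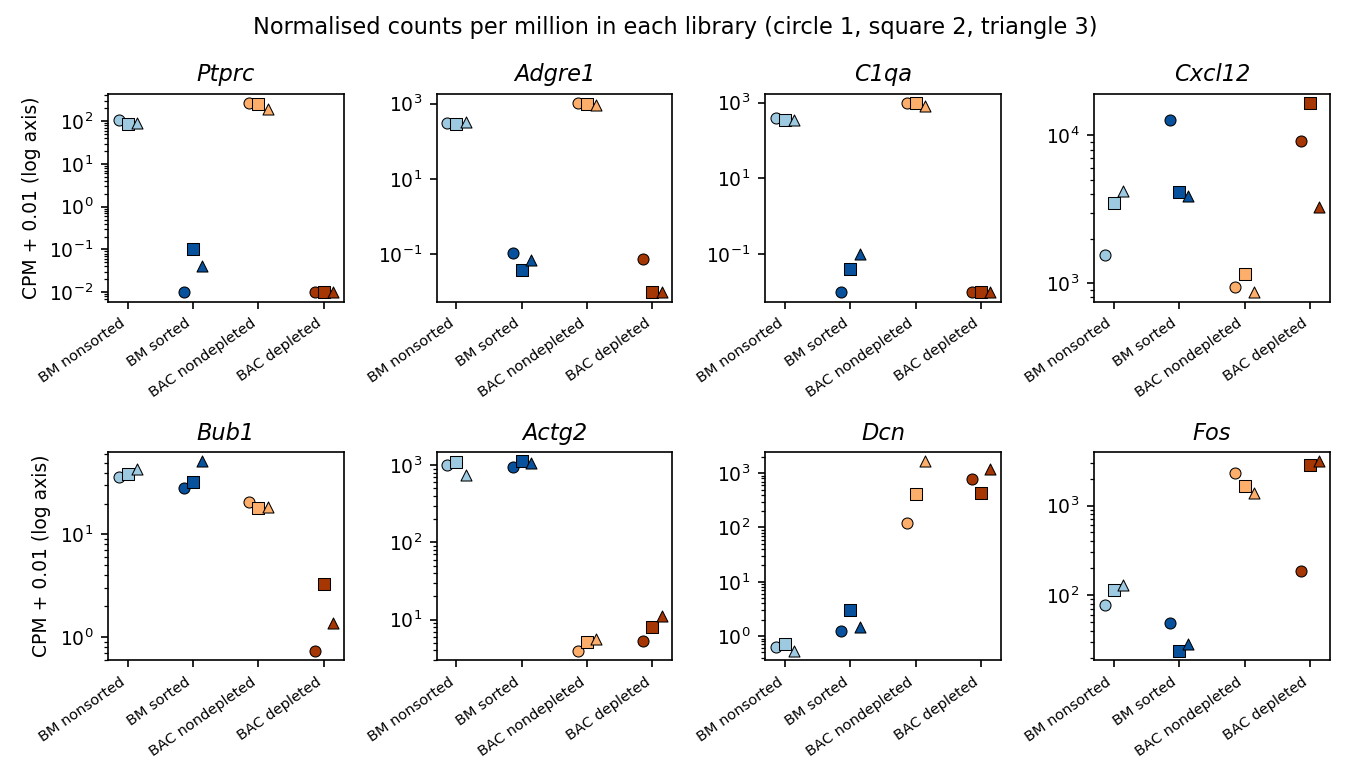
CPM of 8 genes in each library, with 0.01 added so that 0 can be drawn on a log axis. Circles, squares and triangles are replicates 1, 2 and 3 of the group named under the axis. Ptprc, Adgre1 and C1qa are near 0 in both purified groups, Actg2 and Dcn separate marrow from bone-associated cells, Bub1 is lowest in BAC depleted, and Fos is lower in BAC depleted 1 than in the other two libraries of that group.

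Magnetic depletion of the bone-associated cells was compared with the undepleted cells for the same purpose. Macrophage transcripts fell steeply here too, and many other genes differed between the depleted cells and the mixture, in both directions. Ptprc fell from 237 ± 40.0 CPM to 0 counts in all 3 libraries, at least 6663-fold, and Adgre1 was lower by a ratio of 40861 (11311 to 337411). Cxcl12 rose from 984 ± 143 to 9645 ± 6637 CPM, while the mitotic genes Birc5 and Bub1 fell from 16.1 ± 3.80 to 1.47 ± 1.24 and from 19.0 ± 1.30 to 1.81 ± 1.35 CPM.

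By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5863 of 15698 genes differed, 2735 higher and 3128 lower after depletion, and 3175 had a log2 fold change of at least 1 in size. In 46.3% of genes the libraries did not overlap, against 10% by chance. A fit on these 6 libraries alone called 3556 genes. The 6 genes with the largest fitted falls, in an order that rests on the prior count, were C1qa (at least 25816-fold), C1qb (at least 24740-fold), the Fc receptor-like gene Fcrls (at least 19766-fold), Msr1 (at least 6793-fold), Ptprc and Tyrobp (at least 6408-fold), an adaptor of myeloid receptors. The largest rises included Scg2, a secretory granule protein (9.95 ± 0.97, adjusted p = 3.91e-05), Gdf10, a growth factor of the BMP family (8.74 ± 0.87, 4.52e-05), and Car3, a carbonic anhydrase (9.42 ± 1.83, 0.00297). Car3 was uneven, with 10440, 868 and 2754 counts in BAC depleted 1, 2 and 3, against at most 16 in a BAC nondepleted library. Xist also met the rule (12.57 ± 3.26, adjusted p = 0.0132), through library 1 alone. Rasgrf1, a Ras exchange factor (9.36 ± 2.40, 0.0257), and Adipoq, the adipocyte hormone adiponectin (a ratio of 543, interval 186 to 2638, 0.0201), were highest in BAC depleted 1 as well, at 97.7 and 48.3 CPM. Rasgrf1 was lost without BAC nondepleted 1 (adjusted p = 0.0782), 2 (0.0869) or 3 (0.0814), and Adipoq without BAC depleted 1 (0.065), BAC nondepleted 1 (0.0686), 2 (0.0681) or 3 (0.0639). Xist was lost without BAC nondepleted 1 (0.0506).

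All 20 macrophage genes fell on depletion, 20 when adjusted over the list alone, with a camera adjusted p of 3.45e-106 (adjusted p = 0.000162 with an estimated correlation). Of 14 pan-haematopoietic genes 13 fell and 1 did not pass, 14 fell when adjusted over the list alone, and the camera adjusted p was 1.47e-73 (adjusted p = 0.000222 with an estimated correlation). Of 16 inflammatory genes 11 fell and 5 did not pass, 12 fell when adjusted over the list alone, and the camera adjusted p was 1.25e-14 (adjusted p = 0.0218 with an estimated correlation). Ccl4 was at least 2235-fold lower, and the monocyte chemokines Ccl2 (-5.55 ± 0.52, adjusted p = 3.07e-05) and Ccl7 (-4.97 ± 0.48, 3.71e-05) fell with it. Of 5 gate markers 2 fell and 3 did not pass, 1 rose and 4 fell when adjusted over the list alone, and the camera adjusted p was 6.28e-11 (adjusted p = 0.00187 with an estimated correlation). The 2 that fell over all genes, Ptprc and Adgre1, encode antigens that the depletion targeted, so their fall was set by the procedure. Of 7 osteoclast genes 1 rose, 4 fell and 2 did not pass, the same counts when adjusted over the list alone, and the camera adjusted p was 0.00747 (adjusted p = 0.0586 with an estimated correlation). Pf4 alone of 3 erythroid and megakaryocyte genes fell, also 1 when adjusted over the list alone (camera adjusted p = 0.00253; adjusted p = 0.0579 with an estimated correlation). Of 8 dendritic cell and antigen presentation genes 5 fell and 3 did not pass, 7 fell when adjusted over the list alone, and the camera adjusted p was 0.0213 (adjusted p = 0.344 with an estimated correlation).

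Of 20 cell-cycle genes 17 fell on depletion, 0 rose and 3 did not pass, 18 fell when adjusted over the list alone, and the camera adjusted p was 2.44e-08 (adjusted p = 0.353 with an estimated correlation). Birc5 fell by 3.44 ± 0.47 and Bub1 by 3.39 ± 0.45 on the log2 scale (adjusted p = 0.000376 and 0.000304). The mitochondrial share was raised in the same libraries, at 1.82% to 2.62%. Of 16 interferon response genes 8 fell and 8 did not pass, 9 fell when adjusted over the list alone, and the camera adjusted p was 0.0421 (adjusted p = 0.751 with an estimated correlation). This call was lost without BAC depleted 2 (adjusted p = 0.0788) or BAC nondepleted 1 (0.0807).

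The other 19 lists were not called on depletion (camera adjusted p of 0.0507 to 0.949), although single members passed. In the niche factor list Cxcl12 rose (3.29 ± 0.68, adjusted p = 0.00413) with 1 other, and 12 of 14 did not pass, 2 rose when adjusted over the list alone (camera adjusted p = 0.31). Il34, a ligand of the macrophage growth factor receptor, rose (3.83 ± 0.52, adjusted p = 0.000368), within a list of 14 macrophage support factors in which 4 rose, 5 fell and 5 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.552). Among 11 osteoblast genes 5 rose, 1 fell and 5 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.303). Sp7, a transcription factor of osteoblasts, rose (5.33 ± 0.89, adjusted p = 0.00128), and Col1a1, a chain of type I collagen, fell (-1.69 ± 0.33, 0.00281). Among 11 cartilage genes 5 rose and 6 did not pass, 8 rose when adjusted over the list alone (camera adjusted p = 0.0507), led by the collagen gene Col9a1 (7.03 ± 0.83, adjusted p = 0.000149) and the proteoglycan gene Acan (4.95 ± 1.23, 0.0107). Acan had 19, 115 and 862 counts in BAC nondepleted 1, 2 and 3, against 3949, 8574 and 17507 in BAC depleted. The surface antigen genes Alcam (-6.17 ± 0.82, adjusted p = 0.000309) and Cd44 (-2.19 ± 0.30, 0.0004) fell. Of 13 MSC surface genes 2 rose, 2 fell and 9 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.949). The median of this list was 0.54 and its mean -0.13.

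Of the genes called in both purifications, 879 moved the same way, 11 up and 868 down, where 194 would share a direction by chance, and 6 moved in opposite directions, where chance gives 171. The fold changes correlated across genes with Pearson's r = 0.754 and Spearman's rho = 0.449, and genes are not independent replicates.

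**Figure D3:**
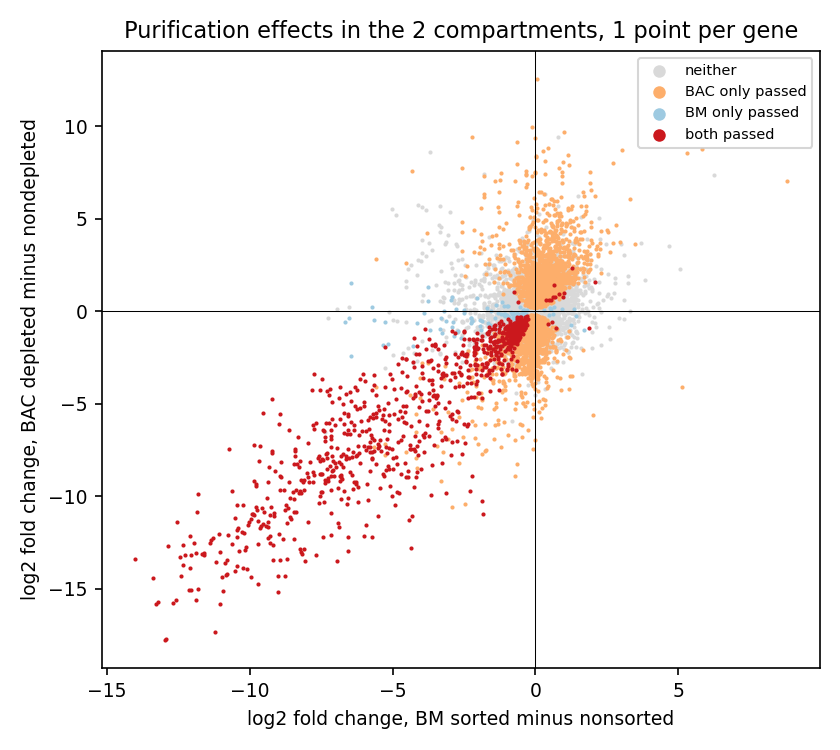
Each point is a gene, with its log2 fold change on sorting of marrow cells on the horizontal axis and on depletion of bone-associated cells on the vertical axis. Red marks genes called in both comparisons, most of which lie in the lower left (868 fell in both), and orange marks genes called on depletion alone.

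The purified cells of both niches were compared to find what separates marrow from bone-associated stroma. Single genes differed widely in both directions, while of the gene lists 5 were called with the preset correlation and 0 with an estimated one. Actg2, a smooth-muscle actin, stood at 1042 ± 84.8 CPM in BM sorted and 8.14 ± 2.90 in BAC depleted. Dcn, which encodes the proteoglycan decorin, stood at 1.90 ± 1.01 and 802 ± 376 CPM. Fos, an immediate-early transcription factor, stood at 33.4 ± 13.0 and 2046 ± 1618 CPM. The compartment, the tissue dissociation and the purification method change together here, so the comparison does not separate them. BM sorted was also selected for CD51 and Sca-1 and against CD31, which BAC depleted was not. The marrow cells were taken after the first passage, and time in culture is not given for the bone-associated cells. Culture and selection can therefore enter every difference below.

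By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7447 of 15698 genes differed, 3591 higher and 3856 lower in BM sorted, and 3862 had a log2 fold change of at least 1 in size. In 52.8% of genes the libraries did not overlap, against 10% by chance. Among the largest fitted rises in BM sorted were Mcpt8, a mast cell and basophil protease (a ratio of 1479, interval 265 to 58434), Gzmd, a granzyme (8.34 ± 0.94, adjusted p = 0.000122), and Krt7, a keratin (8.54 ± 0.78, 5.04e-05). Cd93, a C-type lectin receptor (8.07 ± 0.48, 1.56e-05), Plac8 (8.03 ± 0.70, 3.82e-05) and Slc16a13, a carrier of the monocarboxylate transporter family (a ratio of 249, interval 68.6 to 2061), followed. Granzyme genes have near-identical copies, and the sharing of reads among them was not tested here. The largest fitted falls, higher in BAC depleted, were Cnmd, which encodes the cartilage protein chondromodulin (at least 97109-fold), Thbs4, a thrombospondin (a ratio of 34281, interval 9490 to 283079), and Penk, the enkephalin precursor (-14.23 ± 1.67, adjusted p = 0.000154). Fgf10, a fibroblast growth factor (at least 2586-fold), Chil1 (at least 1493-fold) and Rasgrf1 (at least 1215-fold) were next. Those 3 values and that of Cnmd rest largely on single libraries of BAC depleted, where libraries 1, 2 and 3 held 97.7, 1.38 and 3.04 CPM of Rasgrf1, 8.01, 2.55 and 150 of Chil1, 19.9, 215 and 3.04 of Fgf10, and 1602, 517 and 7899 of Cnmd. Thbs4 varied within BAC depleted from 2.09 CPM in library 2 to 1834 in library 1. Its call was lost without libraries 1 and 3, an alternative chosen after seeing the data. That alternative keeps library 2 alone, against a mean of 0.02 CPM in BM sorted, and cannot measure the spread of BAC depleted.

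Of 12 pericyte and smooth-muscle genes 8 were higher in BM sorted, 1 lower and 3 did not pass, 9 higher and 1 lower when adjusted over the list alone, and the camera adjusted p was 3.08e-05 (adjusted p = 0.696 with an estimated correlation). Actg2 (7.0 ± 0.32, adjusted p = 9.4e-06) and Myh11, a smooth-muscle myosin (3.57 ± 0.82, 0.0054), were higher, and Cspg4, which encodes the pericyte proteoglycan NG2 (-5.03 ± 1.0, 0.00249), was lower. Of 20 cell-cycle genes 18 were higher and 2 did not pass, 18 higher when adjusted over the list alone, and the camera adjusted p was 2.18e-14 (adjusted p = 0.696 with an estimated correlation). Bub1 stood at 4.37 ± 0.46 and Birc5 at 4.19 ± 0.48 (adjusted p = 9.35e-05 and 0.000138). Of 14 immediate-early and heat-shock genes 13 were lower in BM sorted and 1 did not pass, 14 lower when adjusted over the list alone, and the camera adjusted p was 7.89e-05 (adjusted p = 0.952 with an estimated correlation). Fosb (-7.99 ± 1.06, adjusted p = 0.000299) and Fos (-5.94 ± 0.91, 0.000636) led this list, and in BAC depleted 1 Fos stood at 184 CPM, against 2843 and 3111 in libraries 2 and 3. Of 11 cartilage genes 1 was higher, 7 lower and 3 did not pass, 2 higher and 8 lower when adjusted over the list alone, and the camera adjusted p was 0.00592 (adjusted p = 0.84 with an estimated correlation). Ucma, a cartilage matrix protein, was lower by a ratio of 3961 (710 to 156480) and Col9a1 by 1234 (422 to 5987). The size for Ucma rests largely on BAC depleted 3, at 127 CPM against 3.34 and 11.1 in libraries 1 and 2. Of 16 interferon response genes 7 were lower and 9 did not pass, 8 lower when adjusted over the list alone, and the camera adjusted p was 0.0365 (adjusted p = 0.952 with an estimated correlation). That call was lost without BM sorted 2 (adjusted p = 0.0589), BM sorted 3 (0.0707), BAC depleted 2 (0.123) or BAC depleted 3 (0.0838).

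The other 23 lists were not called between the purified groups (camera adjusted p of 0.147 to 0.948). In several of them members went both ways. Of 13 MSC surface genes 4 were higher in BM sorted, 4 lower and 5 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.948). Mcam, which encodes CD146 (4.73 ± 0.65, adjusted p = 0.000352), and Alcam (3.65 ± 0.76, 0.00319) were higher, and Cd34 (-6.59 ± 0.69, 8.48e-05) was lower. In the fibrillar matrix list 4 of 19 were higher, 2 lower and 13 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.932; median 0.20, mean -0.68). Col1a1 was higher (1.97 ± 0.33, adjusted p = 0.000975), and Dcn (-8.71 ± 1.05, 0.000183) and Lum, another small proteoglycan (-9.03 ± 1.69, 0.00185), were lower. Of 14 macrophage support factors 4 were higher, 5 lower and 5 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.948). Cd200, an inhibitory ligand for myeloid cells (3.76 ± 0.80, adjusted p = 0.00377), and Tnfsf11, which encodes RANKL (3.16 ± 0.73, 0.00551), were higher, and Il34 (-5.09 ± 0.56, 0.000106) was lower. Of 11 osteoblast genes 4 were higher, 1 lower and 6 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.355), with the bone alkaline phosphatase Alpl at 3.97 ± 0.65 (adjusted p = 0.000871). Of 14 limb position genes 5 were lower and 9 did not pass, also 5 when adjusted over the list alone (camera adjusted p = 0.246), with Tbx4, a hind-limb transcription factor, at -6.64 ± 1.45 (adjusted p = 0.00422) and Hoxd9 at -5.75 ± 1.02 (0.00139). The gate marker Itgav was higher in BM sorted (0.74 ± 0.21, adjusted p = 0.014), and Ly6a (0.14 ± 0.25, 0.678) and Ly6c1 (0.50 ± 0.42, 0.356) did not pass. The call of Itgav was lost without libraries 1 and 3 of BAC depleted. With 1 library left in that group, this cannot tell a smaller difference from lost power. Ptprc had 4 counts in BM sorted and 0 in BAC depleted, and Adgre1 6 and 2. Of 20 macrophage genes 3 were higher in BM sorted, 4 lower and 13 did not pass, 3 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.932). Among them Fcer1g, a signalling chain of Fc receptors (6.32 ± 1.09, adjusted p = 0.00116), was higher, most in BM sorted 1, and Lyz2, which encodes lysozyme (-2.85 ± 0.63, 0.0045), was lower.

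**Figure D4:**
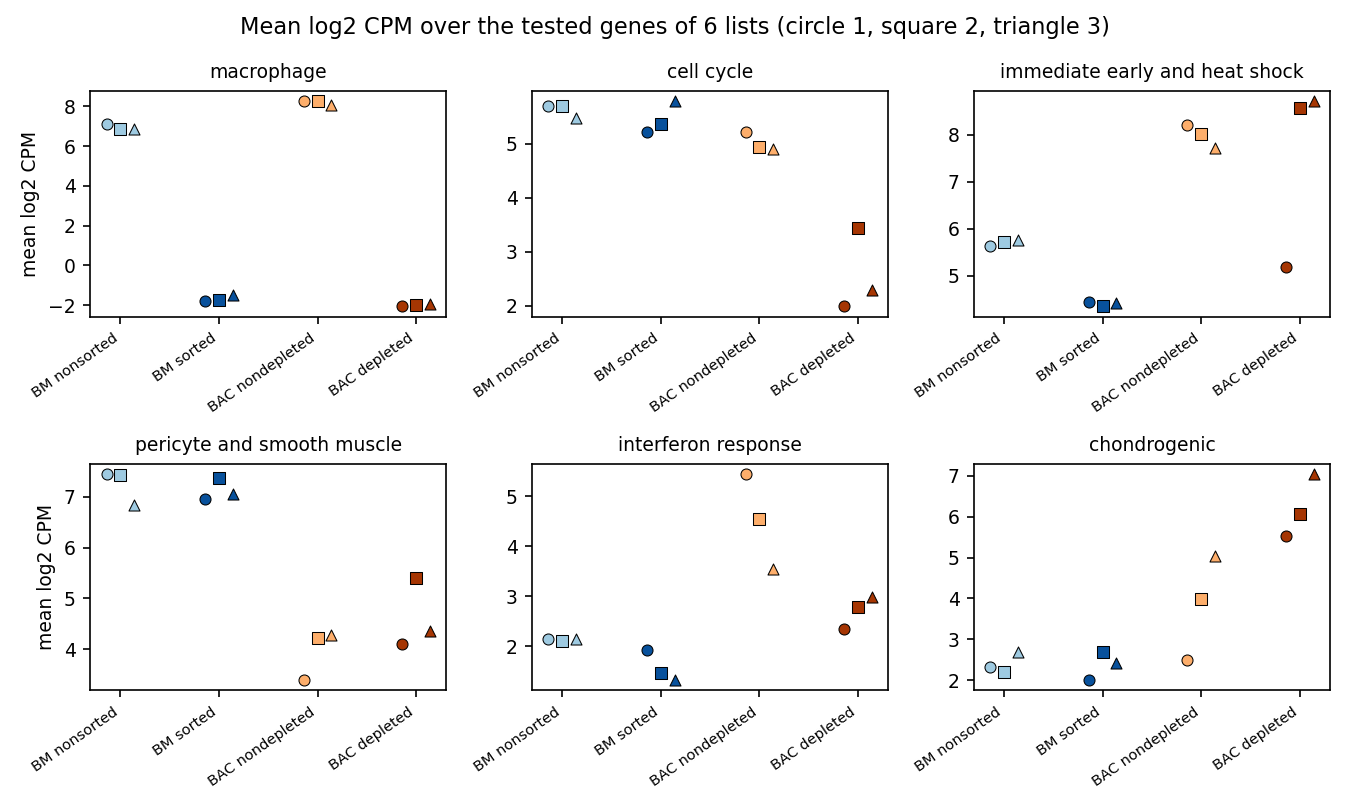
Mean log2 CPM over the tested genes of 6 lists in each library, by group, with circles, squares and triangles for replicates 1, 2 and 3. Macrophage genes are lowest in both purified groups, cell-cycle genes lowest in BAC depleted, and the immediate-early list of BAC depleted 1 (5.18) lies below BAC depleted 2 (8.57) and 3 (8.72).

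The unpurified preparations were compared to see what separates them before sorting or depletion. BM nonsorted had been plated on collagen I and taken after the first passage. BAC nondepleted was digested with collagenase, its time in culture is not given, and it held 2.55 times the macrophage CPM of BM nonsorted. The comparison therefore does not separate the compartment from cell mix, dissociation and culture. The macrophage gene Adgre1 and Ptprc, a gene of all leukocytes, were higher in BAC nondepleted and the smooth-muscle gene Actg2 in BM nonsorted, and of the gene lists 11 were called with the preset correlation and 0 with an estimated one. Adgre1 stood at 302 ± 21.6 CPM in BM nonsorted and 973 ± 62.1 in BAC nondepleted, and Ptprc at 95.7 ± 10.4 and 237 ± 40.0. Actg2 stood at 943 ± 175 and 4.91 ± 0.861 CPM.

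By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4980 of 15698 genes differed, 2339 higher and 2641 lower in BM nonsorted, and 2493 had a log2 fold change of at least 1 in size. In 56.0% of genes the libraries did not overlap, against 10% by chance. Leaving out 1 library lowered the count to 2949 (BM nonsorted 2), 3077 (BAC nondepleted 2) or 3197 (BAC nondepleted 1). The largest fitted rises in BM nonsorted were Ptprb, a phosphatase of endothelial cells (at least 369-fold), Amigo2, an adhesion protein (at least 308-fold), Mcpt8 (at least 272-fold) and Abcc9, a subunit of potassium channels (at least 176-fold). Next came Ptprz1, a receptor phosphatase (a ratio of 861, interval 294 to 4178), and Adgrf5, an adhesion receptor (9.30 ± 0.60, adjusted p = 5.93e-05). The largest fitted falls, higher in BAC nondepleted, were Thbs4 (a ratio of 29935, interval 8287 to 247192), Dpt, which encodes the matrix protein dermatopontin (24060, 4318 to 950368), and Barx1, a homeobox factor (at least 604-fold). Cnmd (-11.82 ± 2.15, adjusted p = 0.0058), Penk (-10.81 ± 1.47, 0.00105) and Serpina6, a steroid-binding protein (at least 292-fold), followed. BAC nondepleted libraries 1, 2 and 3 held 945, 821 and 7.85 CPM of Thbs4, 429, 246 and 35.5 of Dpt, 607, 67.4 and 32.1 of Cnmd, and 17.6, 7.67 and 0.419 of Serpina6. The 6 counts of Cnmd in BM nonsorted all came from library 3. Of Ptprb and Amigo2, BM nonsorted 3 held 24.8 and 18.5 CPM, more than libraries 1 (8.89 and 4.92) and 2 (5.25 and 9.31). Serpina6 was lost without BM nonsorted 1 (adjusted p = 0.0561), 2 (0.0596) or 3 (0.0533) or BAC nondepleted 1 (0.0573) or 2 (0.0566).

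Of 20 macrophage genes 16 were lower in BM nonsorted and 4 did not pass, 16 when adjusted over the list alone, and the camera adjusted p was 2e-12 (adjusted p = 0.0607 with an estimated correlation). The mannose receptor gene Mrc1 (-1.65 ± 0.30, adjusted p = 0.00336) and Adgre1 (-1.69 ± 0.24, 0.00113) led it. Of 14 pan-haematopoietic genes 9 were lower and 5 did not pass, 12 lower when adjusted over the list alone, and the camera adjusted p was 5.67e-07 (adjusted p = 0.0987 with an estimated correlation). Of 16 inflammatory genes 1 was higher, 12 lower and 3 did not pass, the same counts when adjusted over the list alone, and the camera adjusted p was 2.79e-13 (adjusted p = 0.0524 with an estimated correlation). The neutrophil chemokines Cxcl5 and Cxcl2 stood at -6.52 ± 1.04 and -5.42 ± 0.56 (adjusted p = 0.00199 and 0.000338). Of 16 interferon response genes 15 were lower and 1 did not pass, 15 when adjusted over the list alone, and the camera adjusted p was 4.04e-09 (adjusted p = 0.281 with an estimated correlation). Ifit1 stood at -4.43 ± 0.63 and Ifit3 at -4.22 ± 0.60 (adjusted p = 0.00127 and 0.00129). Of 8 dendritic cell and antigen presentation genes 3 were lower and 5 did not pass, 4 lower when adjusted over the list alone, and the camera adjusted p was 0.0125 (adjusted p = 0.281 with an estimated correlation).

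Of 12 pericyte and smooth-muscle genes 10 were higher in BM nonsorted and 2 did not pass, 11 when adjusted over the list alone, and the camera adjusted p was 3.46e-11 (adjusted p = 0.0708 with an estimated correlation). Actg2 stood at 7.59 ± 0.33 and Myh11 at 6.99 ± 1.0 (adjusted p = 5.53e-06 and 0.00132). Of 14 immediate-early and heat-shock genes 7 were lower and 7 did not pass, 9 lower when adjusted over the list alone, and the camera adjusted p was 0.000519 (adjusted p = 0.584 with an estimated correlation). Fosb stood at -6.96 ± 1.02 and Fos at -4.05 ± 0.83 (adjusted p = 0.00145 and 0.0063). The number of lower members was 3 without BM nonsorted 1, BM nonsorted 2, BAC nondepleted 1 or BAC nondepleted 2, 4 without BM nonsorted 3, 6 without BAC nondepleted 3, and 13 without BAC depleted 1, which shares the estimate of the spread. Of 11 osteoblast genes 4 were higher and 7 did not pass, 5 higher and 1 lower when adjusted over the list alone, and the camera adjusted p was 0.0412 (adjusted p = 0.514 with an estimated correlation), with Sp7 at 6.95 ± 0.94 (adjusted p = 0.00103). Of 15 Wnt and BMP modulators 4 were higher and 11 did not pass, also 4 when adjusted over the list alone, and the camera adjusted p was 0.0412 (adjusted p = 0.281 with an estimated correlation). Its member Wnt4, a secreted Wnt ligand, was higher by a ratio of 637 (114 to 25184). Of 8 skeletal muscle genes 3 were higher and 5 did not pass, 6 when adjusted over the list alone, and the camera adjusted p was 0.0363 (adjusted p = 0.591 with an estimated correlation). BM nonsorted 2 stood apart in this list, at a mean log2 CPM of 4.61 against -0.20 and 0.79 in libraries 1 and 3, and without it the list median was 3.26 instead of 5.92. Of 20 cell-cycle genes 4 were higher and 16 did not pass, 2 when adjusted over the list alone, and the camera adjusted p was 0.043 (adjusted p = 0.71 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, stood at 1.89 ± 0.45 (adjusted p = 0.0116). Of these, the osteoblast list was lost without BM nonsorted 2 (adjusted p = 0.0582), BM nonsorted 3 (0.109) or BAC nondepleted 2 (0.0791). The call of the Wnt and BMP modulators was lost without BM nonsorted 3 (0.0515) or BAC nondepleted 1 (0.0563), and that of the cell cycle list without BM nonsorted 1 (0.0833), BM nonsorted 2 (0.0582), BAC nondepleted 2 (0.0791) or BAC nondepleted 3 (0.14).

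The other 17 lists were not called between the unpurified groups (camera adjusted p of 0.0963 to 0.949). Within them Mcam (5.99 ± 0.70, adjusted p = 0.000538) was higher and Cd34 (-3.97 ± 0.58, 0.00147) lower in BM nonsorted. Of 13 MSC surface genes 3 were higher, 3 lower and 7 did not pass, the same counts when adjusted over the list alone (camera adjusted p = 0.949), with a median of -0.20 and a mean of 0.05. The cartilage matrix gene Comp (-7.92 ± 0.60, adjusted p = 0.000113), the protease gene Mmp3 (-8.66 ± 1.27, 0.00145) and the carbonic anhydrase gene Car9 (-6.66 ± 0.80, 0.000609) were lower.

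Across both compartment comparisons, 3282 genes were called in the same direction, 1524 higher in marrow and 1758 higher in bone-associated cells, where chance gives 1184, and 131 in opposite directions, where chance gives 1179. Across genes the fold changes correlated with r = 0.647 and rho = 0.601, and genes are not independent replicates. The number in the same direction was 2072 without BM nonsorted 2 and 2161 without BAC nondepleted 2.

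The difference of the purification effects asks whether sorting of marrow cells and depletion of bone-associated cells acted differently, and equally whether the compartments differed by another amount once purified. The cell-cycle list had the lowest camera adjusted p, 1.42e-19, which was an adjusted p = 0.298 with an estimated correlation, and none of the 11 lists called here kept its call in that setting. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1266 genes were called, 797 with the higher effect in marrow and 469 with the lower, and 842 differed by a log2 value of at least 1. Of 20 cell-cycle genes 15 had the higher effect in marrow and 5 did not pass, 17 when adjusted over the list alone, and the camera adjusted p was 1.42e-19 (adjusted p = 0.298 with an estimated correlation). Birc5 stood at 3.33 ± 0.61 and Bub1 at 3.32 ± 0.59 (adjusted p = 0.0131 and 0.0108). Of 16 hypoxia and glycolysis genes 3 had the higher effect and 13 did not pass, 9 higher and 1 lower when adjusted over the list alone, and the camera adjusted p was 7.31e-05 (adjusted p = 0.298 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, stood at 2.41 ± 0.39 (adjusted p = 0.00795). With 1 library left out the count of 1266 fell to 437 (without BM sorted 3), 507 (BM nonsorted 2), 595 (BM nonsorted 1), 597 (BAC nondepleted 2), 621 (BM sorted 2), 667 (BAC nondepleted 1) and 758 (BM nonsorted 3).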

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

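The splits and all tests of explanations in this part were chosen only after the results they measure were seen, while the contrast for the difference of the purification effects was fixed before.

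The effects of purification differed between marrow and bone-associated cells, by edgeR's test of the difference itself, for 1266 genes. The largest genes with a higher effect in marrow were Cd93 (9.13 ± 0.58, adjusted p = 0.000259), Ctsc (8.44 ± 0.72, 0.000731), Cxcr4 (8.40 ± 0.95, 0.00336), Cd200r4 (7.95 ± 1.84, 0.0387) and Fcer1g (7.66 ± 1.33, 0.0102). These genes are known from myeloid cells, and their group means lay under 0.2 CPM only in BAC depleted, while single libraries departed from this (Cd200r4 at 0 in BM sorted 3, Fcer1g at 0.413 in BAC depleted 1 and Cd93 at 0.283 in BAC depleted 2). Cd93 stood at 49.2 CPM in BM sorted, 177 in BM nonsorted, 0.178 in BAC depleted and 370 in BAC nondepleted, and Fcer1g at 15.4, 117, 0.175 and 294 CPM. In BM sorted Fcer1g was uneven, at 36.4, 7.31 and 2.39 CPM in libraries 1, 2 and 3. The largest with a lower effect in marrow were Angptl1 (-11.93 ± 2.96, 0.0384), Car3 (-11.63 ± 2.20, 0.0147), Scg2 (-10.09 ± 1.20, 0.00237), Col9a1 (-8.46 ± 1.79, 0.0218) and Pla2g5 (-8.37 ± 2.10, 0.0493). Libraries 1, 2 and 3 of BAC depleted held 402, 4150 and 8 counts of Angptl1 and 10440, 868 and 2754 of Car3. In BM nonsorted they held 113, 9 and 8 counts of Angptl1 and 52, 1824 and 107 of Car3. Scg2 stood at 99.6 CPM in BAC depleted and at most 0.912 in the other groups. Cxcr4 and Cd200r4 had 0 counts in BAC depleted and Pla2g5 had 0 in BM sorted, where Col9a1 had 3, so the size of those 4 values rests in part on the prior count.

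Of these calls 5 were lost with 1 library left out, all of them at an adjusted p of 0.0147 to 0.0493 with all libraries. Over the fits with 1 library left out the log2 values kept their direction, at -8.48 to -13.63 for Car3, -7.03 to -11.54 for Col9a1, -8.92 to -13.62 for Angptl1, -6.80 to -8.80 for Pla2g5 and 7.28 to 8.53 for Cd200r4. Car3 was lost without BM sorted 3 (adjusted p = 0.054), and Col9a1 without BM nonsorted 3 (0.203). Angptl1 was lost without BM sorted 1 (0.0808), 2 (0.0840) or 3 (0.108), BM nonsorted 1 (0.141), 2 (0.0611) or 3 (0.0512), or BAC nondepleted 1 (0.0748), 2 (0.0918) or 3 (0.0817). Pla2g5 was lost without BM sorted 1 (0.0769), 2 (0.0909) or 3 (0.102), BM nonsorted 1 (0.108), 2 (0.0826) or 3 (0.0949), or BAC nondepleted 1 (0.0839), 2 (0.0774) or 3 (0.0857). Cd200r4 was lost without BM sorted 1 (0.0714) or 2 (0.0847), BM nonsorted 1 (0.0814), 2 (0.0886) or 3 (0.0760), BAC depleted 1 (0.0521), or BAC nondepleted 1 (0.0717), 2 (0.0780) or 3 (0.0689).

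Of the lists in this contrast, the cell cycle list had the clearest higher effect in marrow (camera adjusted p = 1.42e-19; adjusted p = 0.298 with an estimated correlation; 15 of 20 members, 17 over the list alone). Hypoxia and glycolysis came next (camera adjusted p = 7.31e-05; adjusted p = 0.298 with an estimated correlation; 3 of 16, 9 higher and 1 lower over the list alone). The inflammatory list followed (camera adjusted p = 0.000469; adjusted p = 0.298 with an estimated correlation; 2 of 16, 5 over the list alone), as did the pan-haematopoietic list (0.00090; adjusted p = 0.298 with an estimated correlation; 2 of 14, 5 over the list alone). The macrophage list (camera adjusted p = 0.00148; adjusted p = 0.298 with an estimated correlation) had 3 of 20 members higher, 6 over the list alone, and the dendritic cell list (0.00197; adjusted p = 0.298 with an estimated correlation) 1 of 8, 4 over the list alone. The macrophage genes fell in both compartments, at a median of -10.60 on sorting and -12.32 on depletion (-9.84 and -11.61 with genes at 0 counts set to their bound), so the higher effect in marrow is a smaller fall. Its size rests in part on the prior count, with 8 of 20 members at 0 counts in BAC depleted, and on the start, since BAC nondepleted held 2.55 times the macrophage CPM of BM nonsorted. Between the purified groups neither the macrophage (camera adjusted p = 0.932) nor the pan-haematopoietic list (0.628) was called. The interferon response list (camera adjusted p = 0.0115; adjusted p = 0.614 with an estimated correlation) had 1 of 16, also 1 over the list alone, and was lost without BM sorted 1 (0.0529) or BAC nondepleted 1 (0.124).

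Lists with the lower effect in marrow were chondrogenic (camera adjusted p = 0.0071; adjusted p = 0.31 with an estimated correlation; 2 of 11 members, 2 over the list alone) and 3 with 0 members that passed either way. These were skeletal muscle (camera adjusted p = 0.0108; adjusted p = 0.566 with an estimated correlation; lost without BAC depleted 1, 0.0781) and the other two that follow. Wnt and BMP modulators (camera adjusted p = 0.0269; adjusted p = 0.298 with an estimated correlation; lost without BM sorted 1, 0.0529, or BAC depleted 2, 0.176) came before immediate early and heat shock (0.028; adjusted p = 0.656 with an estimated correlation). That list was lost without BM sorted 1 (0.0529), BAC depleted 2 (0.286), BAC depleted 3 (0.347) or BAC nondepleted 3 (0.0751).

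Splitting the libraries of each comparison of 2 groups in all 10 ways gave as many genes only for the real groups, 1 of 10 in each comparison, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 978 and 0 (BM sorted minus BM nonsorted), 5863 and 2 (BAC depleted minus BAC nondepleted), 7447 and 1 (BM sorted minus BAC depleted) and 4980 and 0 (BM nonsorted minus BAC nondepleted). For the difference of the effects 5 of 100 splits gave at least 1266 genes, the highest other 1910, so chance was not excluded by this count. One of the 5 is the real grouping, and the other 4 kept the BAC groups as they are and regrouped the marrow libraries, so they hold the depletion effect itself. For the overlaps 1 of 100 splits, the real one, reached 879 genes in the purifications and 1 of 100 reached 3282 in the compartment comparisons, the highest other being 0 in both. In every other split at least 1 of the comparisons called no more than 2 genes (purifications) or 1 gene (compartments), so a larger overlap was not possible and the splits say nothing of chance in the overlaps.

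Of 20 cell-cycle genes 17 were lower in BAC depleted than in BAC nondepleted and 18 than in BM sorted, with list calls lost at an estimated correlation (adjusted p = 0.353 and 0.696). A single library does not account for it, since with any 1 library left out at least 17 of 20 were still called lower on depletion. RNA of haematopoietic cells left in BM sorted does not account for the difference from BM sorted, where macrophage-gene CPM was 0.488% of BM nonsorted while cell-cycle CPM kept 91.6%. Loss of dividing haematopoietic cells with the depletion stays open: on sorting of the marrow cultures the list had a median of -0.145 and 0 called genes, but the BAC preparation held 2.55 times the macrophage CPM and its macrophages might divide more. No biological explanation was tested, and compartment and purification method cannot be separated in this design. Time in culture, which is not given for the bone-associated cells, stays open as well.

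Immediate-early genes were higher in BAC depleted than in BM sorted (13 of 14) and in BAC nondepleted than in BM nonsorted (7 of 14), with list calls lost at an estimated correlation (adjusted p = 0.952 and 0.584) and with BAC depleted 1 (mean log2 CPM 5.18) below every BM nonsorted library (5.64 to 5.76). Handling during the magnetic depletion as the whole cause forbids a difference before it, but the 50% of genes called there decide nothing, since the count was 3 without BM nonsorted 1, BM nonsorted 2, BAC nondepleted 1 or BAC nondepleted 2, 4 without BM nonsorted 3, 6 without BAC nondepleted 3 and 13 without BAC depleted 1. A second measure carries less weight, as it was added after the count was seen to change with 1 library left out. It was the gap between the lowest BAC nondepleted and the highest BM nonsorted library, 1.97 log2 units of mean log2 CPM. Neither group was depleted, so a difference was present without that handling. The gap cannot tell how far the handling raised BAC depleted, which stays open. BAC nondepleted held 2.55 times the macrophage CPM of BM nonsorted, and whether macrophage RNA makes the gap was not tested. Between the purified groups, RNA of haematopoietic cells left in BAC depleted (macrophage-gene CPM 0.279% of BAC nondepleted) and a single library (at least 12 of 14 genes called with any 1 left out) do not account for the difference. Collagenase digestion and the compartment itself stay open as untested, because each goes with the BAC groups. Time in culture stays open too, since it is not given for the bone-associated cells.

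Mcpt8 and the granzyme genes Gzmc, Gzmd and Gzme, known from basophils, T cells and NK cells, were present in both marrow groups, at a summed 215 CPM in BM sorted and 114 in BM nonsorted. Gzme and Gzmc were not confined to marrow: BAC depleted 2 held 19.1 CPM of Gzme and 9.97 of Gzmc, against at most 0.382 in BAC depleted 1 and 3, and Gzmc was not called between the purified groups (adjusted p = 0.0748 by edgeR). RNA of such cells in the marrow cultures does not account for it: the sort left 0.042% of Ptprc, which these cells carry, while the lowest BM sorted library held 114% of the mean BM nonsorted level of the 4 genes. Expression in the sorted stromal cells is left as a hypothesis found and examined on the same data. Sharing of reads among granzyme copies was not tested, though it does not apply to Mcpt8 in the same way.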

How the results depend on the processing

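The alternative without replicates 1 and 3 of BAC depleted was chosen after seeing the data, and all others were fixed before. Counts and overlaps stayed within 1.5 times in 97 of 113 alternatives, called lists kept their call in 426 of 484, and named genes kept theirs in 4224 of 4774, with 529 weaker, 19 stronger and 2 reversed. Of the 58 weaker list results, 32 came with an estimated correlation, 24 with a library left out and 2 with the replicate block. Upper quartile scaling moved the median over all genes to 0.127 for BAC depleted minus BAC nondepleted, where 54.3% of calls were then higher, against 46.6%. The rises on marrow sorting numbered 26 and ranged from 6 to 31 with 1 library left out. Depth was similar in all libraries. Recovery of genes changed 2-fold in simulations was 23.9% for marrow sorting and 29.9% for depletion. These simulations gave 70 and 79 edgeR calls, against 978 and 5863 in the data. The adjustment is stricter with few calls, so these shares cannot tell how many small changes were missed in the data. Of the 978 and 5863 calls, 733 and 3175 had a log2 fold change of at least 1 in size, so smaller changes were called too.

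With only the groups compared, the count fell from 5863 to 3556 on BAC depletion and from 7447 to 5446 between the purified groups. It rose from 978 to 1232 for marrow sorting and from 4980 to 6225 between the unpurified groups. The counts fell where BAC depleted takes part, the group with the lowest correlations within it (0.940 to 0.947), and rose elsewhere. The main fit shares its estimate of the spread over all groups, so its 5863 against 978 calls depend in part on that sharing. No further cause was tested. For the difference of the effects they were 2450 with the DESeq2 Wald test, which called 54 unchanged genes in the simulation, 808 with the replicate block, and 2047 without BAC depleted replicates 1 and 3; the cause was not tested. Leaving out 1 library gave 749 to 839 genes for marrow sorting, 4379 to 5990 for depletion, 5678 to 7667 between the purified groups, 2949 to 4188 between the unpurified groups, 437 to 1612 for the difference and 2072 to 3732 for the overlap of the compartment comparisons; the cause was not tested. The replicate block gave 882, 5434, 7065 and 4572 genes in the 4 comparisons of groups. After group means were removed, libraries of the BAC groups correlated at 0.0439 to 0.237 with the same replicate number and -0.157 to 0.0873 with different numbers. Between the BM groups the values were -0.223 to 0.215 and -0.327 to 0.254. The best match had the same number for 2 of 3 BAC depleted and 1 of 3 BM sorted libraries. The closest same-number BAC pair, number 1, differed in the sex-linked genes and so had no shared source. The numbers were not used as pairing.

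A pair of gene results reversed. Wif1 on BAC depletion ranged from -0.34 (without BAC depleted 2, adjusted p = 0.694) to 6.07 (without BAC nondepleted 2) against 5.39 with all libraries, and library 2 held 6436 of its 6520 counts in BAC depleted. Car9 between the purified groups was 0.44 without BAC depleted replicates 1 and 3 against -2.06, since it stood at 76.5, 6.75 and 31.2 CPM in libraries 1, 2 and 3 and that alternative keeps only the lowest.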

Other observations

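The genes in this part were chosen after their values were seen. Keratins of simple epithelia were uneven in the marrow groups: Krt7 stood at 74.1 ± 28.2 CPM in BM sorted and 48.9 ± 17.9 in BM nonsorted, and Krt19 at 53.3 ± 6.63 and 47.3 ± 7.68, while Krt8 had 3 and 6 counts in all and Krt18, its usual partner, 43 and 16. In BAC depleted and BAC nondepleted Krt7 stood at 0.207 ± 0.185 and 0.367 ± 0.381 CPM, and Krt19 at 2.71 ± 4.45 (7.85 in BAC depleted 2) and 1.15 ± 0.551. Krt8 had 3 and 0 counts there and Krt18 0 and 1. By edgeR Krt7 was higher in BM nonsorted than in BAC nondepleted (log2 fold change 7.0 ± 0.71, adjusted p = 0.00032), and so was Krt19 (5.35 ± 1.21, 0.00938).

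A pair of homeobox genes was higher in bone-associated cells, while the limb position list fixed before was not called in either compartment comparison (camera adjusted p = 0.246 and 0.829). Barx1 had 0 counts in all 6 marrow libraries and stood at 16.0 ± 4.98 CPM in BAC depleted and 18.6 ± 9.39 in BAC nondepleted. Hoxd8 stood at 1.35 ± 1.66 CPM in BM sorted, 2.75 ± 3.13 in BM nonsorted, 29.3 ± 9.56 in BAC depleted and 19.1 ± 6.02 in BAC nondepleted (BM sorted minus BAC depleted -4.43 ± 0.99, adjusted p = 0.00489 by edgeR).

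The BAC depleted libraries differed among themselves. The mean log2 CPM of the cartilage list was 5.52, 6.06 and 7.03 in libraries 1, 2 and 3, though not every member was highest in library 3. Col2a1 was highest there, at 20763 CPM against 1650.0 and 3615 in libraries 1 and 2, and so was Ucma, at 127 against 3.34 and 11.1. Comp was highest in library 1, at 8465 against 4412 and 7779.6 CPM, and Col9a1 in library 2, at 54.0 against 15.2 and 51.3. Prg4, a lubricating protein of joint surfaces, stood at 737 CPM in library 3 against 57.4 and 48.2. Cfd, an adipocyte protease, stood at 9.79 CPM in library 1, 0.212 in library 2 and 0 in library 3. Xist stood at 1380.3 CPM in library 1 and at most 0.667 in any other library, and without library 1 the genes that differed on depletion numbered 5498.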
